A study of Mus musculus with 6 samples.

How the data were processed

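Liver RNA of germ-free and conventional Swiss Webster mice on 3 diets was measured on Affymetrix expression arrays. The RNA was pooled by condition and 500 ng of it was amplified from the 3' end, per the labels' protocols. There was 1 array per condition, 6 in all, and the labels give no number of animals per pool. The deposited values are probe-set intensities made with GCRMA, per the submitters' processing notes, which give no version and no settings. The values themselves ran from 4.89 to 74900 and were taken as a linear scale, since their log2 ran from 2.29 to 16.2, the span that the method gives in log2.

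From these intensities the log2 was taken, with no further normalization. Of 45101 probe sets, 64 controls were kept apart for the check of RNA quality. Of the rest, 34945 named 1 gene, 932 named several genes and 9160 named none, and only those that named 1 gene were used. Each of the 18193 genes was represented by its probe set with the highest mean. The 8718 genes with a log2 value of 5 (an intensity of 32) or more on at least 1 array were tested. A value under that level was read as dim, and a fold change against a dim value is given as "at least", computed with the dim value raised to 32. Log2 changes and their errors were computed from the deposited values, dim ones included, so where a gene is dim on 1 side only the direction and the fold given as "at least" hold. Gene symbols were checked against a RefSeq gene table, which changed 0 of them, and no genome build was needed.

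The diets and the 2 colonization states were compared with limma 3.58.1 in R 4.3.3, in an additive model of state and diet over all 6 arrays with moderated t-tests (2 residual degrees of freedom and 4.54 from the prior). P values were adjusted by Benjamini-Hochberg over all tested genes with a threshold of 0.05. Each diet contrast rests on 2 pairs of arrays, 1 pair in each state, and the contrast of the states on 3 pairs. The error of this model is the disagreement between those pairs. It does not hold the spread among animals, which pooling removes, so a p value speaks of these pools and not of mice in general. Any true difference between the states in the response to a diet also counts as error. Single pairs of arrays were compared with no test, as counts of genes that differ 2-fold or more (log2 of 1) and as medians of gene lists. Each such median was placed among those of 10000 random lists drawn from the 200 genes nearest in expression to each member. The genes of a random list were drawn independently, so a list whose members move together reaches an extreme place more easily. These places were not adjusted for the number of lists and comparisons.

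A set of 32 gene lists with 447 entries, of which 312 were tested, was fixed before the data were examined, as were the model, the filter, the thresholds and the rule for the genes that the text names. The 27 lists with 3 or more tested genes were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the lists. Since members of a list move together, camera was repeated with the correlation estimated from the arrays, and fry was also run. With an estimated correlation camera also takes its p value from the 2 residual degrees of freedom, which makes a call hard to reach. A call lost there is thus not by itself a sign that members move together. The named genes are the 6 with the highest and the 6 with the lowest change among those past the threshold in each contrast, the 5 each way in each pair of arrays, a fixed set of bile acid and cholesterol genes, and up to 4 members of each list.

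The alternatives were other filters, the mean of a gene's probe sets, leaving out probe sets marked as less specific, a floor, quantile normalization, centring of the arrays, a trend in the prior, a model without state as a block, only the arrays compared, and the model with each array left out. The analysis was also tested on simulated data with the real 8718 genes, 200 of them changed. Of 50 genes changed by a log2 of 1, 2% were recovered, of 50 changed by 2, 68%, of 50 changed by 4, 98%, and of 50 changed by 6, 96%. There were 9 false calls among 141, and a shifted list of 15 genes gave an adjusted p of 4.13e-15, with 1 other list called. The simulated genes were drawn independently of each other, unlike members of a real list. The simulation therefore does not test whether the preset correlation of 0.01 holds for these lists. It also gave a gene the same error on all 6 arrays, set no lowest value and let the states respond alike. In the data the changes on cholic acid had a scaled median absolute deviation of 0.639 in the conventional and 0.395 in the germ-free pair. The simulated rates of recovery and of false calls may thus not hold for these arrays. The number of arrays limits the precision of every value here.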

Results

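The arrays measured messenger RNA in the livers of germ-free mice, which carry no microbes, and of conventional mice. In each of the 2 states 1 pool came from mice on a purified diet, 1 from mice on a cholic acid diet and 1 from mice on a deoxycholic acid diet, after 2 weeks of feeding and an overnight fast. Cholic acid is a bile acid that the liver makes from cholesterol. Deoxycholic acid lacks the 7-alpha-hydroxyl group of cholic acid and is made from it by gut bacteria. The labels give no sex of the mice and no doses, so the effects of the 2 acids are set side by side as fed. With 1 array per condition there were no replicates, and each log2 change over the 2 states carries the standard error of the model. Between 7922 and 8273 of the 8718 tested genes lay above the filter on each array. The array of the conventional cholic acid pool stood apart in a sign of RNA quality. Its ratio of 3' to 5' signal for Gapdh was 3.48, against 0.874 to 0.952 on the 5 other arrays, and its ratio for beta-actin was 12.7, against 2.83 to 6.19. The same ratio for dap, a bacterial transcript used as an added control, was 125 on this array and 14.1 to 33.9 on the others.

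**Figure D1:**
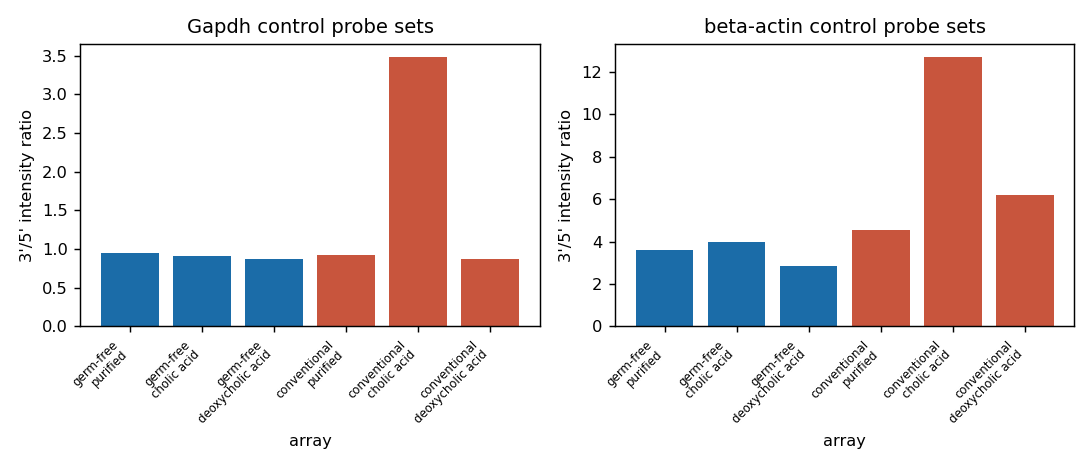
The 3' to 5' intensity ratio of control probe sets on each of the 6 arrays. The Gapdh ratio of the conventional cholic acid array was 3.48, and the other 5 lay between 0.874 and 0.952.

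The cholic acid diet was compared with the purified diet to ask which liver genes change when this bile acid is fed. On cholic acid 3 genes of bile acid synthesis fell. Cyp7a1 (1438743_at), the rate-limiting enzyme of the classical pathway, changed by a log2 of -5.69 ± 0.35 (adjusted p = 0.0043) and was 66.5-fold lower in the germ-free and 40.1-fold lower in the conventional pool. Cyp8b1 (1449309_at), the 12-alpha-hydroxylase needed to make cholic acid, changed by -4.15 ± 0.53 (adjusted p = 0.0355). Cyp7b1 (1421074_at), a hydroxylase of the alternative pathway, changed by -2.45 ± 0.32 (adjusted p = 0.0355). Cyp39a1, which hydroxylates 24-hydroxycholesterol, rose by 2.10 ± 0.29 (adjusted p = 0.0383). Of the 14 measured genes of bile acid synthesis 1 rose and 3 fell, with the same 1 and 3 when adjusted over the list alone, and the list fell as a group (adjusted p = 0.0198). Its median was -0.08 and the call was lost at adjusted p = 0.353 with an estimated correlation. Cyp27a1, which starts the alternative pathway, had a change of -0.41 ± 0.24 (adjusted p = 0.61).

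Genes of bile acid and biliary lipid transport and genes induced by FXR, the nuclear receptor for bile acids, rose as groups on cholic acid. The transport list holds uptake and export genes, which were not tested apart, and 9 of its genes were higher and 3 lower. Slc51b (1454854_at), a subunit of the basolateral bile acid exporter, rose by 2.90 ± 0.33 (adjusted p = 0.0321), at least 6.45-fold in the germ-free and at least 2.79-fold in the conventional pool. Slco1a4, an organic anion uptake carrier, rose by 1.80 ± 0.24 (adjusted p = 0.0383). Nr0b2 (1449854_at), the repressor that FXR induces, was 2.17 ± 0.41 higher (adjusted p = 0.0937), and Abcb11, the bile salt export pump, was 1.65 ± 0.30 higher (adjusted p = 0.086). Of the 12 transport genes 2 rose and 0 fell, or 6 and 2 when adjusted over the list alone, and of the 10 FXR-induced genes 1 rose, or 4 when adjusted over the list alone. Both lists rose as groups, with adjusted p = 0.0307 for transport and 0.000461 for FXR-induced genes, but with adjusted p = 0.353 with an estimated correlation for each. The 2 lists share Abcb11, Abcb4, Slc51a and Slc51b, so they are not separate evidence. Slc51b is the 1 FXR-induced gene past the test and also 1 of the 2 transport genes.

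Of the 15 measured genes of cholesterol synthesis 14 were lower on cholic acid and Sqle, a squalene epoxidase, was dim on all 4 arrays compared. The median was -1.03, and the list fell as a group (adjusted p = 2.66e-09; adjusted p = 0.353 with an estimated correlation). None of the 15 passed alone, and 7 fell when adjusted over the list alone. Fdps (1423418_at), which makes farnesyl diphosphate, was 2.51 ± 0.69 lower (adjusted p = 0.221), Tm7sf2, a sterol reductase, 2.12 ± 0.40 lower (adjusted p = 0.0967), and Msmo1, a sterol oxidase, 2.02 ± 0.51 lower (adjusted p = 0.18). Abcg5 and Abcg8, which together export cholesterol into bile, were 1.14 ± 0.31 (adjusted p = 0.207) and 0.92 (adjusted p = 0.306) higher. The lists of cholesterol uptake (adjusted p = 0.897) and fatty acid synthesis (adjusted p = 0.615) had medians of 0.05 and -0.03, and that of PPAR-alpha targets 0.29 (adjusted p = 0.0618).

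Markers of growth, of bile duct cells and of macrophages rose with these changes. Ccnd1, a cyclin of early cell cycle entry, rose by 4.95 ± 0.38 (adjusted p = 0.0116) and Mcm6, a DNA replication helicase, by 3.07 ± 0.30 (adjusted p = 0.0201), at least 3.12-fold and 4.29-fold in the 2 states. Of 21 listed proliferation genes 20 had a probe set and 11 were tested. Of the 11 tested 4 rose, or 8 when adjusted over the list alone. The list rose (adjusted p = 9.39e-10, and adjusted p = 0.353 with an estimated correlation) with a median of 2.41, or 0.54 once dim values were raised to the filter. Genes dim on both purified arrays were tested only if a bile acid array reached the filter, which favours rises on both bile acid diets. The same holds for the cholangiocyte list (5 of 12 tested) and the chemokine list (6 of 16 tested). Of 5 cholangiocyte markers 3 rose, or 5 when adjusted over the list alone, with a median of 1.86, or 1.11 with dim values at the filter (adjusted p = 2.29e-07; adjusted p = 0.353 with an estimated correlation). Among them were Prom1, a surface protein of progenitor and duct cells, at 3.23 ± 0.32 (adjusted p = 0.0201; at least 1.74-fold and 2.69-fold), and Krt23, a keratin, at 2.50 ± 0.30 (adjusted p = 0.0331). The lists of Kupffer cell markers (median 0.87, adjusted p = 2.27e-07), MHC class II genes (1.44, 0.000461), chemokines and neutrophil genes (1.23, 0.00176), acute phase genes (0.50, 0.000168), interferon-induced genes (0.40, 0.0149) and stellate cell markers (0.41, 0.00907) rose too. For the acute phase list this became adjusted p = 0.385 with an estimated correlation, and for the other 5 lists adjusted p = 0.353 with an estimated correlation. The interferon median was 0.14 in the germ-free pair, or 0.05 with dim values at the filter. It was 0.65 in the conventional pair, which holds the array with the Gapdh ratio of 3.48. Lcn2, an iron-carrier-binding acute phase protein, rose by 4.23 ± 0.39 (adjusted p = 0.0201) and Cd14, a receptor for bacterial lipopolysaccharide, by 3.58 ± 0.52 (adjusted p = 0.0456), at least 7.33-fold and 3.86-fold.

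Male-biased liver genes fell on cholic acid, with all 9 lower, a median of -1.16 and 2 past the test, or 4 when adjusted over the list alone (adjusted p = 3.18e-07; adjusted p = 0.353 with an estimated correlation). Hsd3b5, a steroid dehydrogenase of male liver, changed by -4.50 ± 0.48 (adjusted p = 0.0233). The other gene past the test was Cyp7b1, which is also on the bile acid synthesis list. The 6 female-biased genes rose as a group (median 1.02, adjusted p = 0.0383; adjusted p = 0.353 with an estimated correlation), or by 0.44 with dim values at the filter, and the 3 Y-linked genes had a median of -0.09 (adjusted p = 0.988). The Y-linked median hides opposite shifts, 0.69 in the germ-free and -0.78 in the conventional pair. Pericentral hepatocyte genes fell (median -0.50, adjusted p = 0.0102; adjusted p = 0.389 with an estimated correlation). The lists of periportal genes (0.38, adjusted p = 0.0819), hepatocyte markers (-0.13, adjusted p = 0.263), sinusoidal endothelium (-0.34, adjusted p = 0.0521), gluconeogenesis (-0.34, adjusted p = 0.057), clock genes (0.09, adjusted p = 0.844), xenobiotic metabolism through PXR and CAR (0.30, adjusted p = 0.495), NRF2 targets (0.33, adjusted p = 0.495) and endoplasmic reticulum stress (0.14, adjusted p = 0.532) did not pass. With dim values at the filter the NRF2 median was 0.08. The clock list holds genes of opposite phase, whose shifts can cancel in its median and test. Those 2 phase groups moved apart by 1.005 in the germ-free and 1.407 in the conventional pair. Whether diet, collection time or feeding state moved them was not tested. Outside the lists the highest change was that of Ptgds (1423859_a_at), a prostaglandin D2 synthase, at 8.57 ± 0.46 (adjusted p = 0.0027) and at least 145-fold in the germ-free pool. Ly6d, a surface protein, rose by 5.37 ± 0.35 (adjusted p = 0.0051), Defb1, a defensin, by 4.61 ± 0.24 (adjusted p = 0.0027), and Abcb1a, a drug efflux pump, by 4.17 ± 0.41 (adjusted p = 0.0201). Dio1, the deiodinase that activates thyroid hormone, changed by -4.62 ± 0.60 (adjusted p = 0.0355). Several of these genes were dim on 1 of the diets: Ly6d was at least 36.6-fold and 17.2-fold higher in the germ-free and conventional pools, Defb1 at least 14.2-fold in each, and Abcb1a at least 8.77-fold and 3.49-fold. In all, 49 genes rose and 17 fell, 66 of 8718, and the smallest change among them was 1.73. The count was 0 without the germ-free or without the conventional cholic acid array, and between 127 and 170 without any other one, and it was also 0 with no filter on dim genes. The number of called lists went from 15 to 8 without the germ-free cholic acid array.

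**Figure D2:**
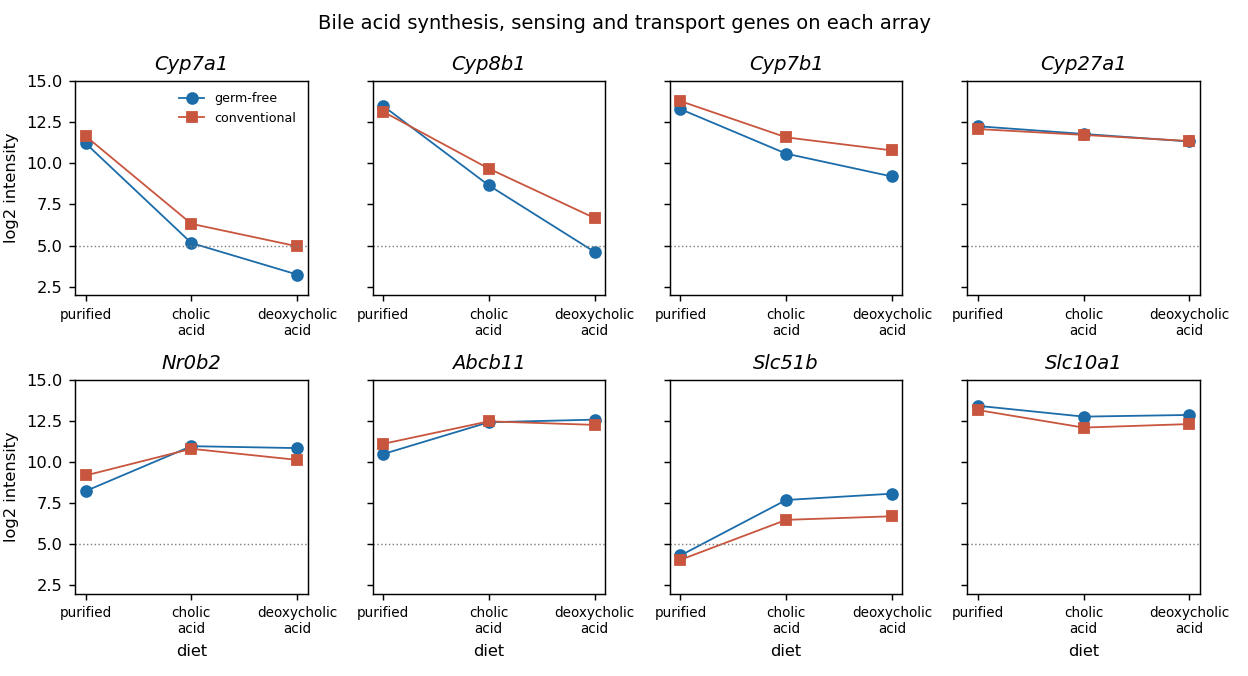
Log2 intensity of bile acid genes on the 6 arrays, 1 point per array, with the log2 value of 5 used as the filter. Cyp7a1 fell from an intensity of 2370 in the germ-free purified pool to 35.7 on cholic acid and 9.46 on deoxycholic acid.

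The deoxycholic acid diet was compared with the purified diet to ask what the microbial product does when fed. The same genes of bile acid synthesis changed as on cholic acid. Cyp7a1 changed by -7.33 ± 0.35 (adjusted p = 0.00165) and was at least 74.2-fold lower in the germ-free and at least 100-fold lower in the conventional pool. Cyp8b1 changed by -7.67 ± 0.53 (adjusted p = 0.00409) and Cyp7b1 by -3.54 ± 0.32 (adjusted p = 0.00664), while Cyp39a1 rose by 1.99 ± 0.29 (adjusted p = 0.0249). Since Cyp8b1 was dim in the germ-free deoxycholic acid pool, the direction of its change holds but not its size. Cyp27a1 had a change of -0.83 ± 0.24 (adjusted p = 0.166). The synthesis list fell with 1 gene up and 3 down, or 2 and 4 when adjusted over the list alone (adjusted p = 0.00741; adjusted p = 0.292 with an estimated correlation). Slc51b rose by 3.20 ± 0.33 (adjusted p = 0.00923), a size that does not hold since it was dim on both purified arrays. Slco1a4 rose by 2.43 ± 0.24 (adjusted p = 0.0084), while Nr0b2 was 1.78 ± 0.41 higher (adjusted p = 0.0889) and Abcb11 1.62 ± 0.30 higher (adjusted p = 0.0521). The FXR-induced list rose, with all 10 genes higher and 1 past the test, or 3 when adjusted over the list alone (adjusted p = 0.000127; adjusted p = 0.253 with an estimated correlation), and the transport list had a median of 0.43 (adjusted p = 0.0717).

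Genes of fat burning and of cholesterol synthesis were lower on deoxycholic acid. Fgf21 (a fasting hormone that PPAR-alpha induces) changed by -3.16 ± 0.33 (adjusted p = 0.00928). It was dim in the conventional deoxycholic acid pool, so the direction of this change holds but not its size. Cyp4a14, a fatty acid hydroxylase, was 2.18 lower (adjusted p = 0.11) and Vnn1, a pantetheinase, 1.99 ± 0.37 lower (adjusted p = 0.0505). Cd36, a fatty acid carrier also on this list, rose by 1.77 ± 0.25 (adjusted p = 0.0246). Of the 22 PPAR-alpha targets 19 were lower, 1 rose and 1 fell, or 1 and 6 when adjusted over the list alone (adjusted p = 4.12e-07; adjusted p = 0.253 with an estimated correlation). Of the 15 cholesterol synthesis genes 12 were lower and none passed, alone or adjusted over the list alone, with a median of -0.53 and a fall as a group (adjusted p = 0.00308; adjusted p = 0.39 with an estimated correlation). That direction rested on the conventional deoxycholic acid array, without which the mean of the list went from -0.45 to 0.21. The lists of cholesterol uptake (median 0.07, adjusted p = 0.392) and fatty acid synthesis (-0.17, adjusted p = 0.285) did not pass.

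Growth, inflammation, macrophage and scar genes rose. Of the 11 proliferation genes 8 rose, or 10 when adjusted over the list alone (adjusted p = 2.35e-12; adjusted p = 0.253 with an estimated correlation), with a median of 2.91, or 1.11 once dim values were raised to the filter. Ccnd1 rose by 4.58 ± 0.38 (adjusted p = 0.00637) and Mki67, a marker of dividing cells, by 3.24 ± 0.36 (adjusted p = 0.0111), at least 2.91-fold and 1.52-fold. The acute phase list rose with a median of 1.23 and 2 genes past the test, or 11 when adjusted over the list alone (adjusted p = 2.2e-09; adjusted p = 0.28 with an estimated correlation), among them Lcn2 at 5.82 ± 0.39 (adjusted p = 0.0038) and Cd14 at 4.83 ± 0.52 (adjusted p = 0.00928). The chemokine and neutrophil list rose with a median of 2.66 (adjusted p = 9.38e-06; adjusted p = 0.28 with an estimated correlation), and Vcam1, an adhesion molecule for leukocytes, rose by 1.93 ± 0.29 (adjusted p = 0.031). Of 11 Kupffer cell markers 2 rose, or 9 when adjusted over the list alone (median 1.08, adjusted p = 4.66e-08; adjusted p = 0.253 with an estimated correlation), and of 5 cholangiocyte markers 3 rose, or 5 when adjusted over the list alone (median 1.92, adjusted p = 1.23e-06; adjusted p = 0.253 with an estimated correlation). Of 9 stellate cell and fibrosis markers 2 rose, or 4 when adjusted over the list alone (median 1.11, adjusted p = 0.000127; adjusted p = 0.28 with an estimated correlation). Col3a1, a fibrillar collagen, rose by 2.53 ± 0.32 (adjusted p = 0.0166). MHC class II genes (median 1.68, adjusted p = 0.000252) and interferon-induced genes (0.59, adjusted p = 0.00311) rose as groups, each at adjusted p = 0.288 with an estimated correlation.

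Detoxification genes rose on deoxycholic acid and male-biased genes fell. Of 19 genes of xenobiotic metabolism through PXR and CAR 3 rose and 3 fell, or 11 and 3 when adjusted over the list alone, and the list rose (median 0.90, adjusted p = 0.00719; adjusted p = 0.28 with an estimated correlation). Gstm3, a glutathione transferase, rose by 5.56 ± 0.48 (adjusted p = 0.00644), at least 60.1-fold in the germ-free and 23.5-fold in the conventional pool, and Gsta2, another, by 3.05 ± 0.39 (adjusted p = 0.0164), while Cyp2c54, a cytochrome P450, changed by -3.57 ± 0.29 (adjusted p = 0.00637). All 9 male-biased genes were lower and 3 fell, or 8 when adjusted over the list alone (median -2.22, adjusted p = 2.99e-11; adjusted p = 0.253 with an estimated correlation). Hsd3b5 changed by -5.56 ± 0.48 (adjusted p = 0.00644) and Elovl3, a fatty acid elongase, by -4.69 ± 0.66 (adjusted p = 0.0238). Cyp7b1, which is also on the bile acid synthesis list, was the remaining gene past the test. Female-biased genes rose as a group (median 1.08, or 0.42 with dim values at the filter, adjusted p = 0.0375; adjusted p = 0.292 with an estimated correlation), and Y-linked genes had a median of 0.21 (adjusted p = 0.69).

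Pericentral genes fell on deoxycholic acid (median -0.80, adjusted p = 2.62e-05), and so did gluconeogenesis (-0.19, adjusted p = 0.0178) and sinusoidal endothelium (-0.32, adjusted p = 0.0136), while periportal genes rose (0.63, adjusted p = 0.0136), each at adjusted p = 0.28 with an estimated correlation. Endoplasmic reticulum stress genes rose (0.39, adjusted p = 0.00455; adjusted p = 0.292 with an estimated correlation). The NRF2 (0.29, or 0.135 with dim values at the filter, adjusted p = 0.116), clock (0.57, adjusted p = 0.12) and hepatocyte (-0.07, adjusted p = 0.181) lists did not pass. The clock genes of opposite phase, which can cancel in that list, moved apart by 2.93 in the germ-free and 0.93 in the conventional pair. Ptgds rose by 8.58 ± 0.46 (adjusted p = 0.00165), Ly6d by 6.41 ± 0.35 (adjusted p = 0.00165) and Spink1, a trypsin inhibitor, by 5.09 ± 0.30 (adjusted p = 0.00217), and in each state these 3 were at least 61.0-fold, 28.6-fold and 8.72-fold higher. In all, 155 genes rose and 49 fell, 204 of 8718. The count was 314 without the germ-free or without the conventional cholic acid array, 127 without the germ-free deoxycholic acid array and 1 with no filter on dim genes.

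The 2 bile acids, which differ by the 7-alpha-hydroxyl group, were compared directly. Cyp2c55 (1419582_at), a cytochrome P450 of xenobiotic metabolism, was the 1 gene that passed. It was higher on deoxycholic than on cholic acid (adjusted p = 0.0424). Its intensity was 84.6 in the germ-free and 85.2 in the conventional deoxycholic acid pool and under 32 in the other 4, so the difference was at least 2.65-fold and 2.66-fold. With dim values raised to a floor it did not pass, and 0 genes did. PPAR-alpha targets fell on deoxycholic against cholic acid, with 21 of 22 lower, a median of -0.86, 0 past the test and 7 fallen when adjusted over the list alone (adjusted p = 7.16e-19; adjusted p = 0.283 with an estimated correlation). The median was -0.50 in the germ-free pair, with 20 of 22 lower, and -1.29 in the conventional pair, with 21 of 22 lower. The conventional pair holds the array with the Gapdh ratio of 3.48, and probe sets of the same gene moved apart by a median of 0.53 in it, against 0.28 in the germ-free pair. Fgf21 was 5.70-fold lower in the germ-free and at least 1.44-fold lower in the conventional pair (adjusted p = 0.412), Vnn1 differed by -2.23 (adjusted p = 0.477), and Acot1, a thioesterase of fatty acid oxidation, by -1.73 (adjusted p = 0.477).

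Of the genes of bile acid synthesis Cyp8b1, Cyp7a1 and Cyp7b1 had lower values on deoxycholic acid. Cyp8b1 was at least 12.6-fold lower in the germ-free pair and had intensities of 102 against 819 in the conventional pair (adjusted p = 0.477). Cyp7a1 was dim in both deoxycholic acid pools and at least 1.12-fold and 2.50-fold lower there (adjusted p = 0.719). Cyp7b1 differed by -1.09 (95% interval -1.86 to -0.32, for this gene alone, adjusted p = 0.987). The interval for Nr0b2 ran from -1.38 to 0.59, for Abcb11 from -0.76 to 0.70 and for Slc51b from -0.50 to 1.10. A p that misses the threshold does not show that the 2 acids act alike. The interval lay within 2-fold either way for 5424 of 8718 genes (62.2%), and 328 genes had an unadjusted p under 0.05, where 436 would be expected by chance. The bile acid synthesis list fell on deoxycholic against cholic acid (median -0.15, adjusted p = 0.0143), with a median of -0.31 in the germ-free and 0.03 in the conventional pair, as did male-biased (-0.64, or -0.38 with dim values at the filter, adjusted p = 2.33e-06) and pericentral genes (-0.28, adjusted p = 0.00225). Cholesterol synthesis (0.58, adjusted p = 2.55e-05), xenobiotic metabolism (0.43, adjusted p = 0.000348), acute phase (0.73, adjusted p = 3.13e-06), chemokines (1.72, adjusted p = 0.00391), proliferation (0.66, adjusted p = 0.00225), endoplasmic reticulum stress (0.29, adjusted p = 0.00572), clock (0.35, adjusted p = 0.00786) and stellate cell lists (0.41, adjusted p = 0.00932) rose. Each of these 11 lists had adjusted p = 0.497 with an estimated correlation. The count of 1 gene became 0 without either cholic acid array or without the conventional deoxycholic acid array, 14 without the germ-free deoxycholic acid array and 59 without either purified array. The number of called lists went from 12 to 1 without the germ-free cholic acid array and to 3 without the germ-free deoxycholic acid array.

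**Figure D3:**
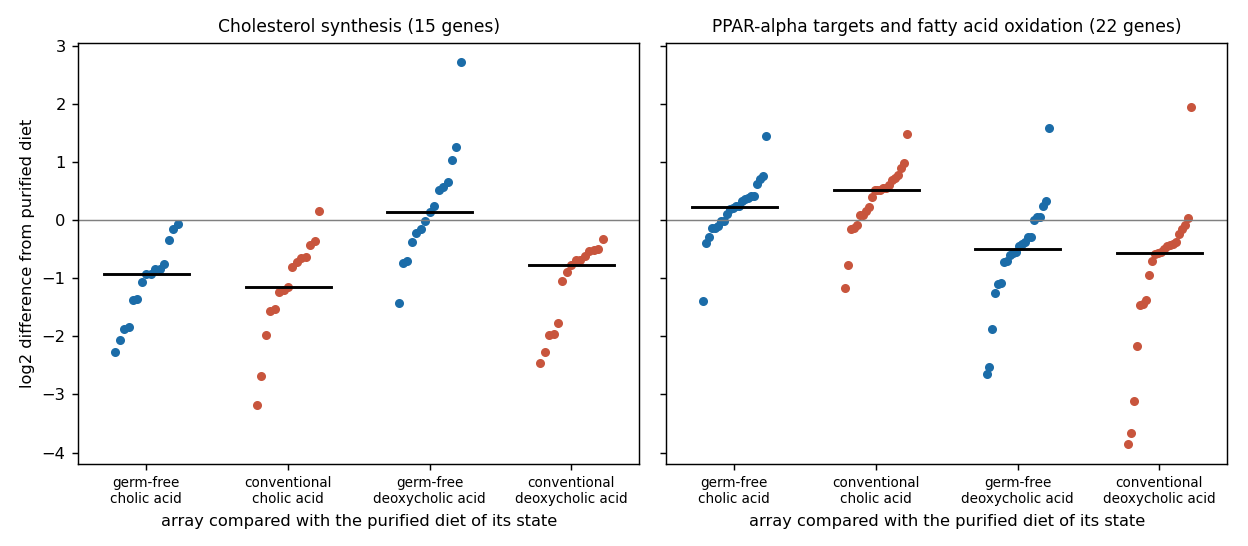
Log2 difference from the purified diet of the same state for each gene of the cholesterol synthesis and PPAR-alpha lists in germ-free and conventional pools, 1 point per gene with the median as a line. PPAR-alpha targets had a median of 0.23 and 0.52 on cholic acid and -0.49 and -0.56 on deoxycholic acid.

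The responses of the germ-free and the conventional pools to the same diet were set against each other to ask whether microbes alter them. These comparisons have 1 array on each side and were not tested. Cyp7a1, Ptgds and Ccnd1 moved the same way in both states on both diets. So did all 66 and all 204 genes past the test on the 2 diets. The test selects for such agreement, so these genes do not bear on the question. On deoxycholic acid the 2 states' changes correlated at r = 0.737 over all genes, and 451 genes differed 2-fold or more in the same direction in both against 3 in opposite directions (99.3% the same way, exact 95% interval 98.1% to 99.9%). On cholic acid r was 0.384, with 277 genes the same way and 7 opposite (97.5%, 94.99% to 99.00%). Both intervals take the genes as independent, which they are not, so they are likely too narrow. The responses were no closer within a diet than across diets on cholic acid: germ-free cholic with conventional deoxycholic acid gave r = 0.676, and germ-free deoxycholic with conventional cholic acid r = 0.528. Independent lists of the same sizes would share 40.5 genes up and 10.1 down on cholic acid, where 209 and 68 were shared. The conventional cholic acid pair holds the array with the Gapdh ratio of 3.48, and it had 1301 genes at 2-fold or more against 637 in the germ-free pair. On deoxycholic acid the counts were 704 conventional and 946 germ-free.

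Cholesterol synthesis genes had a median of 0.14 on deoxycholic acid in the germ-free pool and of -0.78 in the conventional pool. The difference of 1.16, with 14 of 15 genes higher in the germ-free response, was 0.75 with dim values at the filter, and it was not tested. On cholic acid the medians were -0.93 and -1.15. Fdps was 2.05-fold higher on deoxycholic acid in the germ-free and at least 3.48-fold lower in the conventional pool. Idi1, an isomerase of the same pathway, had intensities of 250 and 248 in the germ-free purified and deoxycholic acid pools and of 210 and 38.1 in the conventional ones. In the germ-free pools cholesterol synthesis was 1.15 higher on deoxycholic than on cholic acid, above all 10000 random lists, and in the conventional pools 0.11 higher. The list of chemokines and neutrophil genes had a median of 1.78 in the germ-free and 3.20 in the conventional pool, though the median of its 6 differences between the states' responses was 0.30, higher in the germ-free pool. S100a8, a calcium-binding protein of neutrophils, had an intensity of 4600 in the conventional deoxycholic acid pool against 52.3 on the purified diet. Of the acute phase genes, Orm2, a plasma glycoprotein, was 76.3-fold and Saa2, a serum amyloid, 46.5-fold higher in that pool. The acute phase list had a median of 1.77 in the conventional and 0.70 in the germ-free pool.

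Conventional and germ-free pools were compared over the 3 diets to ask what differs with the microbiota. The design text speaks of 2 strains while every label gives Swiss Webster, and a difference of stock would not be separated from colonization here. Sult1e1 (1420447_at), which sulfates and inactivates estrogens, was lower in conventional pools by 2.58 ± 0.21 (adjusted p = 0.0442), with intensities of 25.8, 28.5 and 27.3 against 158, 141 and 194, at least 4.94-fold, 4.39-fold and 6.06-fold. Fam171b (1454965_at), a membrane protein gene, was higher by 3.27 ± 0.25 (adjusted p = 0.0442), at least 2.28-fold, 1.74-fold and 3.68-fold on the purified, cholic acid and deoxycholic acid diets. They were the only 2 of 8718 genes past the test, and 698 had an unadjusted p under 0.05. With dim values raised to a floor, or with no filter, neither passed. Vldlr, a lipoprotein receptor, was 3.18 higher (adjusted p = 0.131), and Cidec, a lipid droplet protein, 2.87 lower (adjusted p = 0.181). Cyp7a1 was 1.11 higher (adjusted p = 0.444), Cyp7b1 1.02 higher (adjusted p = 0.444) and Fdps 1.75 lower (adjusted p = 0.534) in conventional pools. Igha and Jchain, which encode parts of immunoglobulin A of plasma cells, were 1.78 ± 0.32 (adjusted p = 0.26) and 1.76 ± 0.39 (adjusted p = 0.346) higher. Cholesterol synthesis (median -0.46, adjusted p = 0.0173) and PPAR-alpha targets (-0.29, adjusted p = 0.00334) fell, with 0 genes past the test in either and 0 and 3 when adjusted over the list alone. On the purified, cholic acid and deoxycholic acid diets the medians were -0.197, 0 and -1.001 for cholesterol synthesis and -0.26, 0.002 and -0.49 for PPAR-alpha targets, whose median over the diets was -0.19 with dim values at the filter. Male-biased genes (0.26, adjusted p = 0.026), Kupffer cell markers (0.17, adjusted p = 0.0229) and sinusoidal endothelium (0.26, adjusted p = 0.0233) rose, and all 5 lists had adjusted p = 0.956 with an estimated correlation. The Kupffer and endothelial medians were 0.72 and 0.65 in the cholic acid pair, which holds the array with the Gapdh ratio of 3.48, 0.12 and 0.20 in the purified pair, and -0.003 and -0.026 in the deoxycholic acid pair. The mean of the male-biased list went from 0.33 to -0.02 without either deoxycholic acid array. The count of 2 genes became 0 without either cholic acid array and 81 without either purified array, and that of 5 lists became 9 without either purified array. On the purified diet alone 190 genes were higher and 107 lower in the conventional pool by 2-fold or more, on cholic acid 374 and 508, and on deoxycholic acid 232 and 353.

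**Figure D4:**
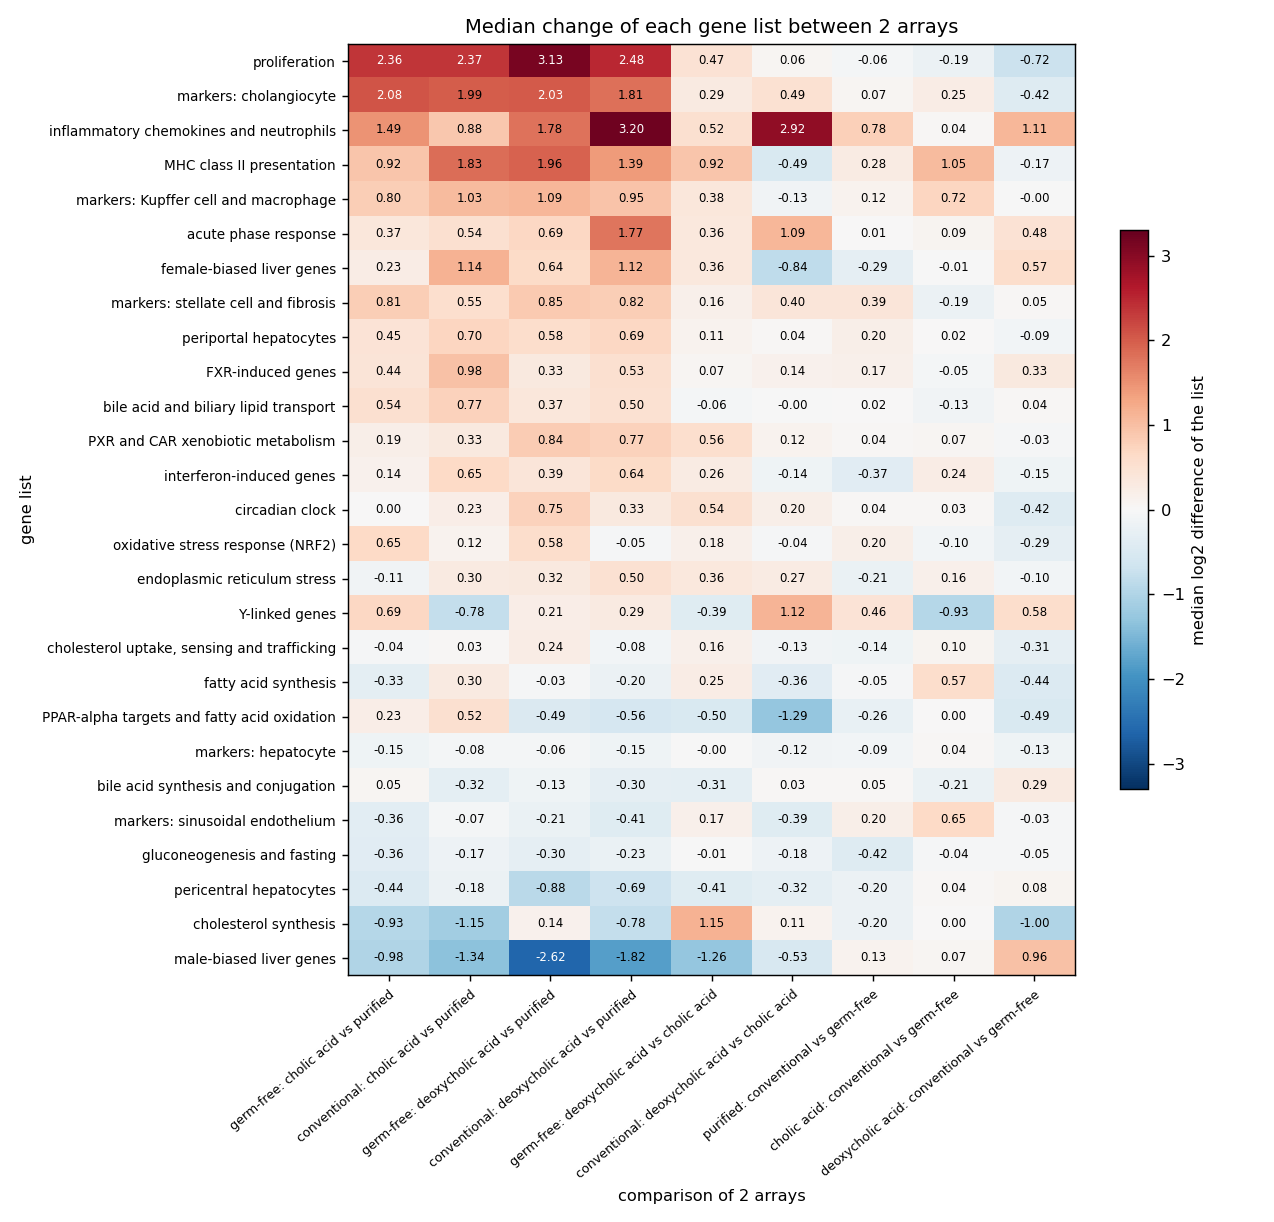
Median log2 difference of each gene list (vertical axis) in 9 comparisons of 2 arrays (horizontal axis), in colour and as a number. Proliferation genes lay between 2.36 and 3.13 in the 4 comparisons with the purified diet, and at 0.28, 0.54, 1.54 and 0.74 from left to right once dim values were raised to the filter.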

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

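Of the tests in this part, those of the sex of the mice, of the time of day, of degradation behind the male-biased genes and of the RNA quality of the arrays behind the cholesterol result were chosen only after the result was seen, and so was the test on genes bright on the purified arrays. Those of RNA degradation and of hepatocyte share behind the array that stands apart, and of genes bright on every array, were written before they were run. From here on, ± after a median is a spread over the genes of a list. It is their scaled median absolute deviation divided by the square root of their number. This takes the genes as independent, which they are not, and does not measure the spread among arrays or animals.

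The conventional cholic acid array had a Gapdh 3' to 5' ratio of 3.48 in control probe sets that no comparison uses, and the highest of the other 5 was 0.952. RNA degradation may lie behind it, since probe sets of the same gene moved apart more on this array: their median gap was 0.55 (95% interval 0.53 to 0.57) in conventional cholic acid against purified and at most 0.37 in the other 3 diet comparisons. The dap control had a high ratio there as well (125). Dap is added to the RNA, so earlier degradation of the liver RNA alone would not raise its ratio. A fault in the amplification could raise it and give the same gap. For the liver genes the 2 were not separated. A smaller share of hepatocytes in the sampled piece predicted that every other cell type would be higher there than in the germ-free pool, but stellate markers had a median of -0.19 ± 0.10 beside 0.72 ± 0.10 for Kupffer markers. The 1301 changes of 2-fold or more in this pool were not separated from this fault.

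Fdps was 1.04 log2 higher on deoxycholic acid than on the purified diet in the germ-free pool. In the conventional one its deposited values differed by -2.27, but it was dim on deoxycholic acid, so only the direction holds. The 2 directions were opposite, and the difference was not tested. Sqle, a squalene epoxidase of the same pathway, had deposited values that differ by 2.73 and -1.05, but it lay above the filter only on the germ-free deoxycholic acid array, so the first is at least 1.25-fold and the second compares 2 dim values and gives no direction. Over the 15 genes of cholesterol synthesis, with dim values raised to the filter, the germ-free median was 0.14 and the conventional one -0.69.

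Weak probe sets could make part of this cholesterol pattern. Over the 9 genes at a log2 of 7 or more on both purified arrays, with dim values at the filter, the median difference between the states was still 0.57 ± 0.29. It was positive for 8 of the 9, where weak probe sets as all of it predicted a median near 0. Genes of the list move together (estimated correlation 0.448), so this error is likely too small to decide. The 6 genes that bright on every array gave 0.46, but that choice drops genes that fell and decides nothing. The conventional cholic acid array takes no part in this difference, and the Gapdh ratios of the 4 arrays that do lie within 1.09 of each other. Their beta-actin ratios ran from 2.83 to 6.19, highest on the conventional deoxycholic acid array. Probe sets of the same gene moved apart by 0.32 in its comparison with the purified diet, less than the 0.364 of the germ-free one. Between the states, however, they moved apart by 0.493 on deoxycholic acid and by 0.363 on the purified diet. These gaps point opposite ways, so degradation there stays open. The germ-free deoxycholic acid pool may have been collected at another time of day or in another feeding state: clock genes of opposite phase moved apart there by 1.65 against cholic acid, and by -0.19 in the conventional pair. Against the purified diet they moved apart by 1.00 and 1.41 on cholic acid and by 2.93 and 0.93 on deoxycholic acid (germ-free and conventional). Between conventional and germ-free pools they moved apart by -2.15 on deoxycholic acid, -0.30 on the purified diet and -0.06 on cholic acid. The largest clock shift between the states was thus on the diet with the pattern. Smaller clock shifts against the purified diet were also present in pools without the pattern, and this account stays open. The shifts against the purified diet all went the same way. A difference in collection time or feeding state was therefore not separated from diet in any contrast of a bile acid with the purified diet.

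Male-biased genes fell on both bile acid diets. Female-biased genes rose as a group, with 0 genes past the test, or 2 on each diet when adjusted over the list alone. In the germ-free cholic acid pool their median was 0.23, or 0 with dim values at the filter. More females in the bile acid pools could lower male-biased genes. Y-linked genes should then have dropped by as much, but their median lay above that of the male-biased genes by 0.56 at the least and by 2.83 at the most in the 4 diet comparisons. The smallest gap was that of the conventional cholic acid pair, where the 3 Y-linked genes had a median of -0.78 (SD 0.46), and the labels give no sex. In the germ-free cholic acid pair their median was 0.69 (SD 0.049), and between the states on cholic acid it was -0.93. The conventional cholic acid array, with its high Gapdh ratio, enters the -0.78 and the -0.93. A difference between the cholic acid pools in their share of males stays open. RNA degradation in the conventional cholic acid pool could not give the fall on cholic acid alone, since the germ-free pair, which does not hold that array, had a median of -0.98 ± 0.29. In the model of the 5 other arrays the median was -0.63 ± 0.19, against -1.16 with all 6, so a part of the fall from that array stays open. The fall on deoxycholic acid takes nothing from that array, so leaving it out could not move its median of -2.22 and tests nothing. No biological explanation was tested.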

How the results depend on the processing

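The results rest on 6 arrays, and leaving out 1 array leaves 1 residual degree of freedom, so a lone array of a condition is taken to vary like the others. Arrays are paired in the main model by state and by diet. No paired analysis by replicate number was possible because the labels number no replicates. Of the counts and shares led with, 153 values in other settings stayed close to the main value and 69 moved, and of the correlations 15 stayed and 1 moved. Of the called lists 642 values kept call and direction, 83 lost the call and 3 turned. Of the named genes 2200 kept both, 28 gained and 181 lost the call, 49 untested ones moved and 25 turned. The cause was not tested for any change below, except that fewer arrays or genes entered where the setting says so. The 66 genes on cholic acid became 0 with no filter, 43 with the mean of probe sets, 39 without the state as block, 145 with only the arrays of the 2 diets and 0 to 170 with each array left out. The 204 on deoxycholic acid became 1 with no filter, 314 with only 2 diets and 127 to 314 with each array left out. The 1 gene between the acids became 0 with no filter, at the filter of log2 7, with a mean filter, with the floor and with a trend, 2 without less specific probe sets, 59 with only 2 diets and 0 to 59 with each array left out. The 2 genes between states became 0 with no filter, a mean filter, the mean of probe sets, the floor or without both cholic acid arrays, 1 at log2 7 or without the block, 5 without less specific probe sets, 81 without both purified arrays and 0 to 81 with each array left out. Called lists became 0 with an estimated correlation in all 4 contrasts. That setting also leaves the test 2 degrees of freedom, so the loss does not show that correlation caused it. The PPAR-alpha list between the acids had an estimated correlation of 0.00484, under the preset 0.01. Its unadjusted camera p still went from 2.65e-20 to 0.0105. With fry the called lists were 4, 4, 0 and 0. With each array left out they were 8 to 16 on cholic acid (15 in the main analysis), 15 to 19 on deoxycholic acid (20), 1 to 13 between the acids (12) and 4 to 9 between the states (5, and 3 with no filter). The counts at 2-fold between 2 arrays moved at the filter of log2 7 to 413 and 592 in germ-free pools on cholic and deoxycholic acid, 463 in conventional ones on deoxycholic acid, 158 between acids in germ-free pools, and 171 and 351 between states on purified diet and deoxycholic acid. With the mean of probe sets they were 381 and 720 on cholic acid and 624 and 464 on deoxycholic acid (germ-free and conventional), 553 between acids in conventional pools, and 165, 487 and 335 between states. With each array left out some values turned sign. The mean of the cholesterol synthesis list on deoxycholic acid ranged from -1.11 to 0.21 and that of the male-biased list between states from -0.02 to 0.53. Sqle ranged from -1.85 to 0.54 on cholic acid, from -0.80 to 2.48 on deoxycholic acid, from -0.14 to 3.13 between acids and from -1.39 to 0.50 between states. Srebf2 ranged from -1.08 to 0.10 on cholic acid, from -0.29 to 0.83 on deoxycholic acid and from -0.692 to 0.074 between states. Between the acids Nr0b2 ranged from -0.95 to 0.16, Nr1h4 from -0.351 to 0.046, Abcb11 from -0.36 to 0.30, Slc51b from -0.019 to 0.618, Abcg5 from -0.43 to 0.12 and Abcg8 from -0.753 to 0.004. Between states Nr0b2 ranged from -0.44 to 0.39 and Abcb11 from -0.13 to 0.34. Without both purified arrays Nr0b2 was -0.44 and Abcb11 -0.13, and without both deoxycholic acid arrays Sqle was 0.50 and Srebf2 0.074. Centring the arrays moved the median of all genes by up to -0.129, in germ-free deoxycholic acid against purified. Signal over background limits the dim genes, as Sqle lay above the filter on 1 array only.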

Other observations

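In the conventional deoxycholic acid pool 3 neutrophil genes, chosen for their high values, stood above all other arrays. Prtn3, a protease of immature neutrophils, had an intensity of 457 there and of 6.85 to 6.99 elsewhere, at least 14.3-fold higher than on the purified diet. S100a9, the partner of S100a8, had an intensity of 2200 there and of 21.5 to 74.4 elsewhere, and Ngp, a granule protein of developing neutrophils, had 194 there and 5.28 to 10.1 elsewhere. In the conventional cholic acid pool Cyp2b13 and Cyp2b9, 2 female-biased cytochromes P450, were at least 3.83-fold and 14.2-fold higher than in the germ-free one, and Fos, an early response gene, had a value of -3.22, all on the array with the Gapdh ratio of 3.48. Thrsp, a regulator of fat synthesis, was 3.78 higher on deoxycholic than on cholic acid in germ-free pools. None of these single pairs was tested.

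On the purified diet interferon-induced genes had a median of -0.37 in the conventional against the germ-free pool, or -0.28 with dim values at the filter. The -0.37 was lower than all but 0.04% of random lists. Usp18, a brake on interferon signalling, was at -1.98 and Oas1a, a sensor of viral RNA, at -1.23. Gluconeogenesis genes had a median of -0.42 (0.02% of random lists lower). Both were picked from many lists and comparisons with no adjustment, and the random lists do not hold genes that move together. NRF2 targets, the genes of the oxidative stress response, had medians of 0.65 on cholic and 0.58 on deoxycholic acid in germ-free pools, and of 0.12 and -0.05 in conventional ones. The conventional cholic acid value rests on the array with the Gapdh ratio of 3.48. With dim values at the filter the germ-free medians were 0.47 and 0.30 and the conventional ones -0.11 and -0.05. Fatty acid synthesis genes had a median of 0.57 in the conventional against the germ-free pool on cholic acid, a comparison that rests on the array with the Gapdh ratio of 3.48, and had a median of -0.44 on deoxycholic acid. Red cell contamination was read from Alas2 alone, 1.28 higher in conventional pools (adjusted p = 0.536), and no tested gene marked T cells, pancreas, fat or muscle.

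The following hypothesis and its test were chosen only after the result was seen, while the test of splits was written before it was run. Gut bacteria turn cholic into deoxycholic acid, so enough conversion in conventional mice could give the PPAR-alpha list its deoxycholic acid response on the cholic acid diet. That predicted a median below 0 in conventional cholic acid against purified, but the median was 0.52 ± 0.10. The prediction was not met, yet the value rests on 1 array, the one with the Gapdh ratio of 3.48, so the hypothesis stays open. Over all genes the germ-free difference between the 2 acids correlated with the conventional cholic acid response at 0.382 and with the conventional deoxycholic acid response at 0.332, which does not separate the 2 diets.

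The 2 genes that passed between conventional and germ-free pools were set against other groupings of the arrays. Of the 10 ways to split the 6 arrays 3 against 3, with the diet kept in the model, 1, the real one, gave 2 genes, and the best other split gave 1. With 10 splits the share is never under 0.1, too few for a share under 0.05.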
